A study of Mus musculus with 6 samples.

How the data were processed

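Sorted bone marrow cells without lineage markers and with Sca1 were taken from WT and DKO mice, and each group had 3 pools of RNA, per the labels. The labels' protocols give RNA extraction with a column kit and biotin labelling by the standard Affymetrix method. The deposited table holds 1 linear intensity value (MAS5 signal) per probe set and array. MAS5 was used per the submitters' processing notes, which give no version, and its detection calls were not used here. In the deposited values the trimmed mean of every array, with 2% left out at each end, was 500, so the authors' scaling was kept as it was. The 6 columns were matched to the labels by sample, and 0 columns belonged to other samples. Replicates are separate pools of mice per the labels. No batch, date or slide is given in the sources used here.

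The table has 45101 probe sets. From it 64 control probe sets were left out, which left 45037, of which 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 are unnamed there. Of those with 1 symbol, 34741 were matched by gene identifier to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. No gene was named from a probe set with several symbols. Genome positions served only to find genes near the targeted loci, and since the build behind the arrays is not named, none is printed.

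Signals were turned into log2(signal + 16). The 40% of probe sets with the lowest mean of these log2 values over the 6 arrays were left out. The limit on that mean equals a signal of about 53.2. Fold changes on this scale understate changes of dim genes. The remaining 27022 probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), DKO against WT, with no block and two-sided. Adjusted p-values are Benjamini-Hochberg values over the 27022, with a threshold of 0.05; "rose", "fell" and "changed" are used for values past it. Errors of log2 differences are standard errors and those of signals are SD, with n = 3 arrays per group. A gene is represented by its probe set with the highest mean among those with its symbol alone, which gave 11529 genes. Of 66 other tested probe sets of 83 named genes, 4 had the opposite sign, and 2 of these belonged to a gene that passed, Nr4a2.

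Before the data were examined, 32 gene lists and the rule for naming genes were fixed. Named are the 3 NR4A genes, the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, and in each list up to 4 members past the threshold by smallest p, or else the 2 members with the smallest p. Lists in which neither the list nor a member passed may be given without members. Other genes named beside a list are members outside this rule, chosen after their values were seen. Lists with at least 5 measured members, 30 in all, were tested with limma's camera at its preset correlation of 0.01, adjusted over the 30, with camera at an estimated correlation and fry beside it. The NR4A and sex-linked lists were given gene by gene. Genes near the targeted loci were counted within 10 Mb with Fisher's exact test.

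The alternatives were pseudocounts of 1 and 64, no filter or a filter of 60%, quantile normalization, median centring, eBayes without a trend, array quality weights, a replicate block, each array left out in turn, an adjusted p threshold of 0.10, the mean over a gene's probe sets, and windows of 5 and 20 Mb or calls at p 0.01 around the loci. Median centring moved the median log2 difference of all tested probe sets from -0.05 to 0.06, a shift of 0.11, and moves every list median by as much; printed differences are those of the authors' scaling. The fit was tested on simulated arrays with 27022 probe sets and 3 against 3 samples. Of 50 probe sets changed at each size, it recovered 6% at a log2 change of 1, 54% at 2, 86% at 3 and 92% at 4, and called 2 unchanged probe sets. On simulated lists of 20 genes, 4 of 200 unshifted lists had p under 0.05 and 50 of 50 shifted by 0.5 did. The simulated genes were independent, so this says nothing about correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.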

Results

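RNA of haematopoietic stem cell-enriched mouse bone marrow was measured on 6 Affymetrix mouse expression arrays. The cells lacked lineage markers and carried Sca1, a surface protein of stem and early progenitor cells. They were sorted from wild-type (WT) mice and from mice without Nr4a1 and Nr4a3 (DKO), a pair of related nuclear receptors of the NR4A family. Each group had 3 arrays, and each array held RNA pooled from 10 to 20 mice aged 2 to 3 weeks, so the spread between arrays is that between pools. The DKO mice had a mixed C57BL/6 and 129SvJ background per the labels, which give no strain for the WT mice. The comparison asks which transcripts in these cells depend on the 2 receptors. The number of arrays limits the precision. Median signals per array lay between 91.7 and 123 after the authors' scaling to a trimmed mean of 500.

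Array pairs of the same group correlated at 0.898 to 0.933 in WT and 0.927 to 0.944 in DKO, across probe sets, and pairs of different groups at 0.874 to 0.912. The first principal component held 35.3% of the variance and separated the groups. The second held 22.8% and set WT replicate 2, at -75.3, apart from WT replicates 1 and 3, at 43.8 and 55.0. WT replicate 2 also had the highest mean level of the neutrophil, B lineage and erythroid lists. On the log2 scale, relative to each gene's mean over the arrays, these were 1.28, 1.34 and 1.56, against -1.27, -0.48 and -1.03 in WT replicate 3.

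Nr4a1 signal was nearly lost in DKO, at 21.4 ± 12.9 (SD, n = 3) against 1065 ± 230 (n = 3) in WT. The log2 difference, DKO minus WT, was -4.89 ± 0.42 (SE), adjusted p = 1.95e-04. The 3 probe sets of Nr4a3 were too dim to pass the filter on low values, with WT means of 51.2, 52.9 and 98.9 and DKO means of 8.50, 47.2 and 19.1. Their log2 differences of -1.53, -0.19 and -1.51 did not pass the threshold when all probe sets were tested (adjusted p = 0.197, 0.935 and 0.401), so Nr4a3 does not check the labels. Whether any of these probes lies in a deleted part of its gene is not given in the sources used here. The third family member, Nr4a2, fell at its brightest probe set, from 1994 ± 631 to 668 ± 230 (-1.57 ± 0.32, adjusted p = 0.0383). With an array left out that call held in 1 of 6 cases, without WT replicate 3, and adjusted p reached 0.164. The 5 other Nr4a2 probe sets did not pass. Of these 5, 3 were lower and 2 dim ones higher (0.54 and 0.73).

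**Figure D1:**
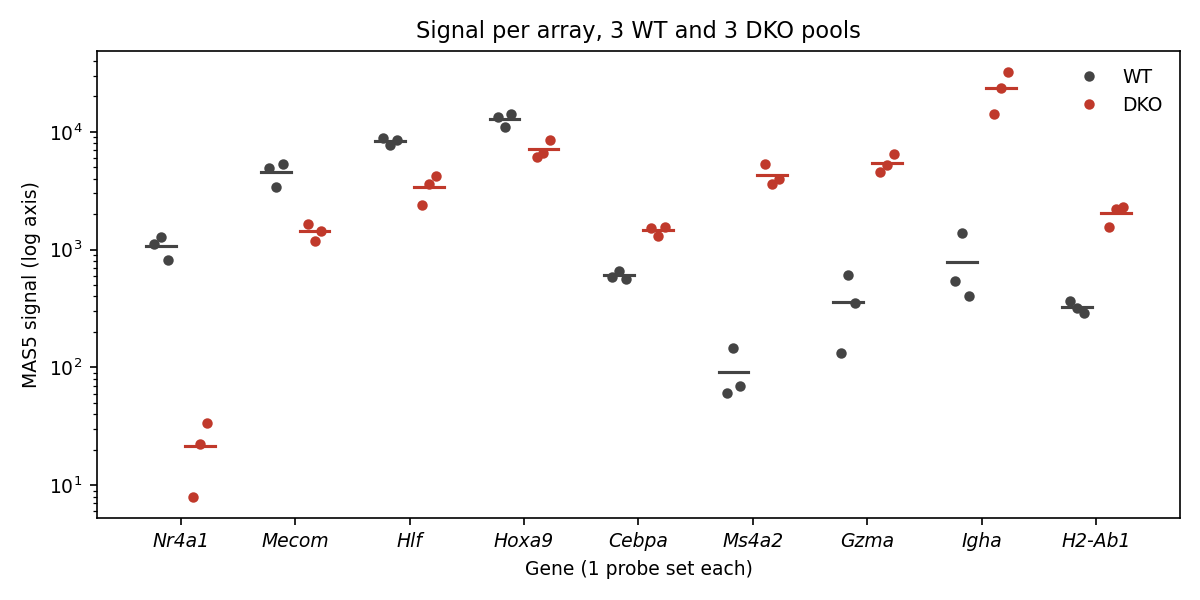
MAS5 signal (log axis) of 9 genes in each of the 3 WT (grey) and 3 DKO (red) pools, with the mean of each group as a line. Signals of Nr4a1, Mecom, Hlf and Hoxa9 were lower, and those of Cebpa, Ms4a2, Gzma, Igha and H2-Ab1 higher, in every DKO pool than in any WT pool.

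In DKO cells the lists of mast cell, basophil and eosinophil genes and of T and NK cell genes were higher, and the stem cell list was lower. With an estimated correlation the call of the mast cell, basophil and eosinophil list was lost (adjusted p = 0.0865), while the T and NK cell and stem cell lists had an adjusted p of 0.0190. Of 27022 probe sets tested, 370 changed, 218 higher and 152 lower in DKO. They covered 197 of 11529 genes, 124 higher (62.9%) and 73 lower, and 73 rises and 22 falls were at least 4-fold on the log2(signal + 16) scale. The rises and falls were 119 and 46 (72.1% higher) with median centring, 54 and 17 without WT replicate 1, 196 and 72 without WT replicate 2 and 30 and 10 without an intensity trend. The order of the 12 largest rises depends on the offset of 16, since several WT signals were near the floor. Among them was Ms4a2, the beta chain of the high-affinity IgE receptor, at 4297 ± 894 against 92.0 ± 46.9 (log2 5.38 ± 0.33, adjusted p = 1.59e-05). Igha, the IgA heavy chain, rose by log2 4.99 ± 0.40, the J chain gene Jchain by 4.13 ± 0.38 and the light chain gene Igkv6-15 by 4.05 ± 0.70. Probes of immunoglobulin segments can bind related segments, so Igha and Igkv6-15 may stand for several transcripts. The granzymes Gzmb and Gzma rose by 4.72 ± 0.49 and 4.06 ± 0.41, and Tbx21, a regulator of type 1 lymphocytes, by 4.13 ± 0.51. The basophil protease Mcpt8 rose by 3.88 ± 0.41, the lipoxygenase Alox15 by 3.70 ± 0.44, the lipase Lipg by 4.08 ± 0.51, the carbonic anhydrase Car4 by 4.05 ± 0.64 and the secreted hormone Stc2 by 3.87 ± 0.51. Adjusted p of these 12 rises was at most 0.0171.

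Besides Nr4a1, the 12 largest falls on the log2(signal + 16) scale included those of Dcstamp, a gene of cell fusion, at -3.03 ± 0.64, and of the zinc finger gene Zfp612 at -2.96 ± 0.45. Gdpd3 had the brightest WT signal among the 12, 2362 ± 103 against 389 ± 120 in DKO (-2.59 ± 0.26, adjusted p = 8.73e-04). The other falls were Rab6b (-2.79 ± 0.58), the growth factor receptor gene Gfra1 (-2.60 ± 0.48), Csgalnact1 (-2.57 ± 0.45), the leukaemia gene Mn1 (-2.45 ± 0.37), Tagln (-2.44 ± 0.52), Sytl4 (-2.42 ± 0.47), the transporter gene Slc16a9 (-2.41 ± 0.38) and the microRNA host gene Mir99ahg (-2.32 ± 0.41), with adjusted p up to 0.0475. Of the 12 rises, 10 stayed past the threshold whichever array was left out (exceptions Car4 and Igkv6-15), and of the 12 falls 4 did (Nr4a1, Zfp612, Gdpd3 and Mn1). The probe set of Csgalnact1 lay between -2.94 and -2.16 with an array left out and stayed past the threshold in 3 of 6 cases, with adjusted p up to 0.0995. In 4 settings a second Csgalnact1 probe set, at -0.99 (adjusted p = 0.377) with all arrays, was the brighter and stood for the gene. It was at -0.76 (adjusted p = 0.658) without WT replicate 1, -1.49 (adjusted p = 0.122) without WT replicate 2, -1.07 with a pseudocount of 1 and -0.88 with quantile normalization. With a pseudocount of 64 Dcstamp was at -1.96, Rab6b at -1.82, Gfra1 at -1.64 and Tagln at -1.48. The count of changed genes was 71 without WT replicate 1, 71 without DKO replicate 1, 97 without DKO replicate 2, 53 without DKO replicate 3, 117 with no filter on low values, 40 without an intensity trend and 308 with array quality weights. In all 197 changed genes the groups did not overlap, as was so for 22.0% of all genes, against 10% by chance.

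Transcripts of haematopoietic stem cells were lower in DKO. Of 28 measured genes of the stem cell list, 24 were lower, and the median log2 difference was -0.98. Over all probe sets 9 fell and 0 rose, and 20 fell when adjusted over the list alone. Mecom, a transcription factor that stem cells need, fell from 4564 ± 1008 to 1425 ± 230 (log2 -1.66 ± 0.22, adjusted p = 0.00390). Mllt3, a maintenance factor of stem cells, fell by log2 1.29 (-1.29 ± 0.18, adjusted p = 0.00458), the transcription factor Hlf changed by -1.33 ± 0.21 (adjusted p = 0.00936) and the surface receptor gene Procr by -1.66 ± 0.27 (adjusted p = 0.0111). Slamf1, Gata2, Gfi1b and Ifitm3 were the 4 members not lower, at 0.37, 0.18, 0.03 and 0.21. With camera the adjusted p of the list was 9.58e-15, and adjusted p = 0.0190 with an estimated correlation. Its mean level was 0.40 to 0.58 in the WT arrays and -0.60 to -0.44 in the DKO arrays.

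Genes of the HOX and MEIS list, many of them drivers of leukaemia when overexpressed, were lower too. The list holds homeobox genes and others, such as Flt3, Mn1 and Evi2a. Of 12 measured genes, 11 were lower with a median of -1.01; 5 fell over all probe sets and 7 when adjusted over the list alone. Besides Mn1 these were the receptor gene Flt3 (-1.54 ± 0.25, adjusted p = 0.0108), Hoxa9 (12834 ± 1619 against 7075 ± 1206, -0.86 ± 0.16, adjusted p = 0.0259), Hoxa3 (-1.18 ± 0.23, adjusted p = 0.0270) and Meis1. The adjusted p of the list was 1.88e-08, and 0.0327 with an estimated correlation. It shares 4 genes with the stem cell list. The other 8, among them Flt3, Mn1 and Evi2a, had a median of -1.17, with 7 lower. Mecom, Mllt3 and Mn1 stayed past the threshold whichever array was left out, Hlf and Procr in 5 of 6 cases, Flt3 in 3, Hoxa9 in 2 and Hoxa3 in 1. Without an intensity trend Mn1 passed (adjusted p = 0.0486). Mecom, Mllt3, Procr and Hlf did not pass there (adjusted p = 0.0694, 0.0797, 0.0893 and 0.131), nor did Flt3, Hoxa3 and Hoxa9 (adjusted p = 0.0660, 0.135 and 0.227).

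Mast cell, basophil and eosinophil transcripts were higher in DKO. All 15 measured genes of that list, out of 22 fixed, were higher, with a median log2 difference of 2.80. A gene dim in WT could pass the filter through its DKO signals, so this count and median may lean toward rises. Fcer1a, at 10.2 ± 5.9 in WT, was measured in 3 of 6 cases with an array left out. Of the 15, 7 rose over all probe sets and 12 when adjusted over the list alone. Besides Ms4a2 and Mcpt8 these were the protease gene Cpa3 (3.65 ± 0.40, adjusted p = 0.00103), the IgE receptor gene Fcer1a (2.94 ± 0.46, adjusted p = 0.00932, and 1.73 with a pseudocount of 64), the eosinophil receptor gene Ccr3, the histamine enzyme gene Hdc and the eosinophil peroxidase gene Epx. The mast cell chymase Cma1 and tryptase Tpsb2 did not pass, at 0.08 and 0.65. Camera gave an adjusted p of 2.20e-16 for the list, and adjusted p = 0.0865 with an estimated correlation. Within WT its mean level was highest in WT replicate 2, at -0.54 against -1.45 and -1.89, and the DKO arrays lay at 1.15 to 1.49.

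T cell and natural killer (NK) cell transcripts were higher as well, in 19 of 22 measured genes, with a median of 1.73. Over all probe sets 7 rose, and 15 when adjusted over the list alone. They were Gzma, Gzmb, the chemokine Ccl5 (2.95 ± 0.41, adjusted p = 0.00439), the surface marker Thy1 (2.36 ± 0.33, adjusted p = 0.00545) and the CD3 chain genes of the T cell receptor complex, Cd3e, Cd3d and Cd3g. Cd247, Lat and Rora were lower, at -0.41, -0.26 and -0.21, and did not pass. The adjusted p of the list was 6.51e-13, and 0.0190 with an estimated correlation. Its mean level lay between -1.10 and -0.71 in WT and between 0.75 and 1.06 in DKO.

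**Figure D2:**
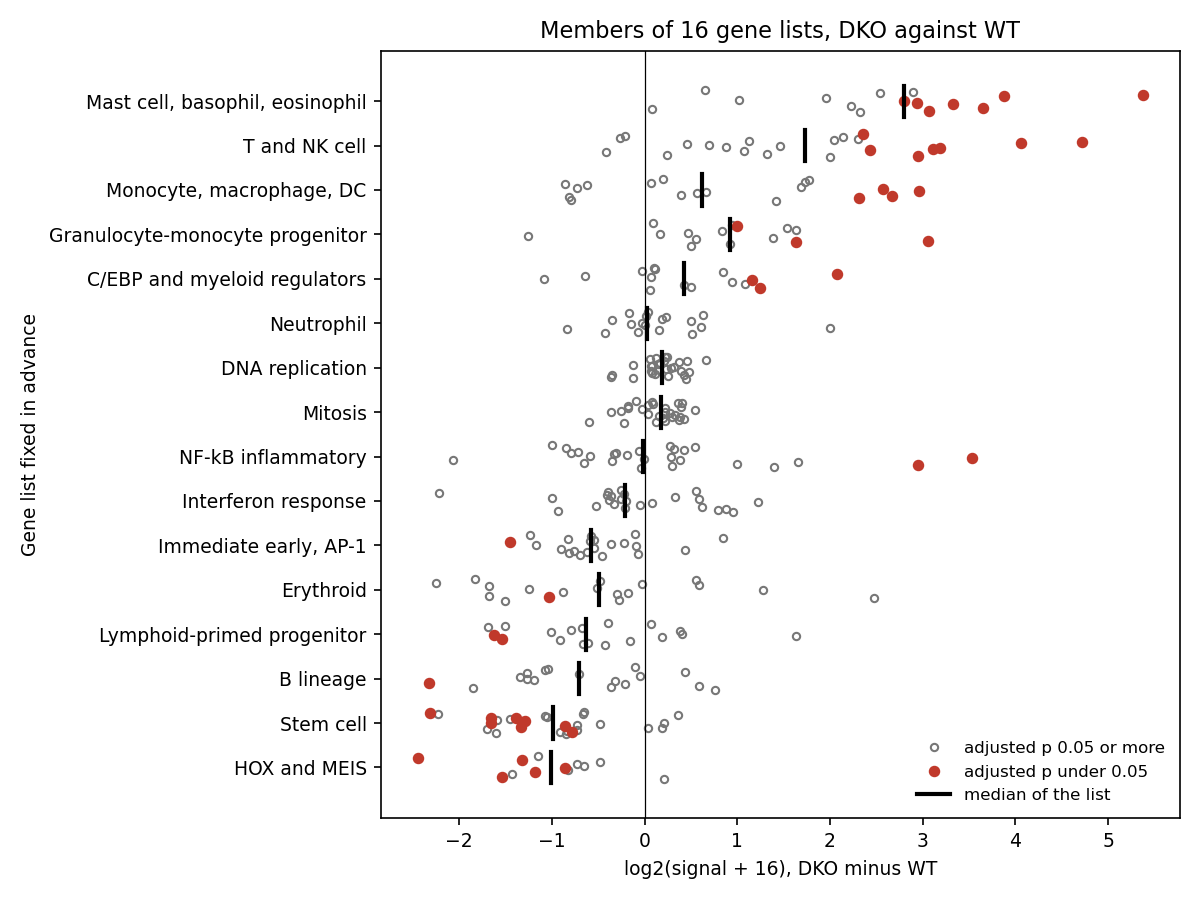
Differences in log2(signal + 16), DKO minus WT, of the measured members of 16 gene lists fixed before the data were examined; each point is a gene, filled where its adjusted p over all probe sets was under 0.05, and the bar is the median of the list. Medians ranged from 2.80 (mast cell, basophil, eosinophil) to -1.01 (HOX and MEIS).

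Genes of granulocyte and monocyte development were partly higher. In the granulocyte-monocyte progenitor list 14 of 15 genes were higher, with a median of 0.92. Over all probe sets 3 rose, and 9 rose and 1 fell when adjusted over the list alone. The risen genes were cathepsin G, Ctsg (3.06 ± 0.44, adjusted p = 0.00602), Plac8 (1.00 ± 0.16, adjusted p = 0.00902) and Cst7 (1.64 ± 0.36, adjusted p = 0.0487), the last also made by cytotoxic lymphocytes. Mpo, Prtn3 and Elane did not pass over all probe sets, at 0.84, 0.95 and 0.55 (adjusted p = 0.167, 0.249 and 0.775). The groups overlapped for Mpo and Elane. The list's adjusted p was 3.81e-06, and 0.229 with an estimated correlation. Its mean level in WT replicate 2, 0.16, lay above that in DKO replicate 2, 0.07, with WT replicates 1 and 3 at -0.60 and -0.91. Another split of the arrays gave a larger shift, 0.96 against 0.90. Among 15 myeloid regulators 3 rose over all probe sets and over the list alone: Cebpa, a regulator of granulocyte fate, by 1.24 ± 0.23 (adjusted p = 0.0242), Irf8, a regulator of monocytes and dendritic cells, by 2.07 ± 0.37 (adjusted p = 0.0194), and Csf2rb, a shared chain of the GM-CSF, IL-3 and IL-5 receptors, by 1.16 ± 0.19 (adjusted p = 0.0117). Their list had a median of 0.42 and an adjusted p of 0.00369 (0.235 with an estimated correlation). The median was 0.22 without WT replicate 1 and 0.23 without DKO replicate 2, and the mean level was 0.09 in WT replicate 2 against -0.39 in both other WT arrays. With an array left out Ctsg stayed past the threshold in 5 of 6 cases, Plac8 in 4, Csf2rb in 3, Irf8 in 2, Cebpa in 1 and Cst7 in 0.

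In the monocyte, macrophage and dendritic cell list 13 of 18 genes were higher (median 0.62, adjusted p = 5.00e-04, and 0.521 with an estimated correlation), 4 rose over all probe sets and 7 when adjusted over the list alone. The chemokine receptor gene Ccr2 rose by 2.32 ± 0.26 (adjusted p = 0.00152). The other 3 were the antigen presentation genes H2-Ab1 (2.57 ± 0.26, adjusted p = 8.73e-04), H2-Aa (2.96 ± 0.39, adjusted p = 0.00340) and Cd74 (2.67 ± 0.56, adjusted p = 0.0427), which B cells express too. Ccr2, H2-Ab1 and H2-Aa stayed past the threshold whichever array was left out, but Cd74 in 1 of 6 cases and in 6 of 9 other settings, with adjusted p up to 0.172. The call of H2-Aa was lost without an intensity trend (adjusted p = 0.0555). Lyz2, Cd68 and C1qb did not pass, at -0.86, -0.82 and -0.80. The mean level of the list in WT replicate 2, 0.46, lay among the DKO arrays (0.35 to 0.46) and apart from WT replicates 1 and 3 (-0.79 and -0.94). Its median was 1.43 without WT replicate 2, 0.25 without WT replicate 3 (adjusted p = 0.0373) and 0.29 with no filter on low values. The neutrophil list had a median of 0.02 with 0 of 18 genes past the threshold over all probe sets and 1 when adjusted over the list alone. The smallest p in it were those of Ifitm6 (2.00 ± 0.49, adjusted p = 0.0756) and Anxa1 (0.51 ± 0.23, adjusted p = 0.355). Its adjusted p of 0.461 depended on single WT arrays. Without WT replicate 2 it was 4.42e-06 with a median of 0.85, and without WT replicate 3 it was 0.0393 with a median of -0.66.

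Early lymphoid genes were lower. In the lymphoid-primed progenitor list 13 of 18 genes were lower (median -0.64, adjusted p = 4.95e-04, and 0.0865 with an estimated correlation). Over all probe sets Flt3 and Il12a (-1.63 ± 0.36, adjusted p = 0.0498) fell and 0 rose, and when adjusted over the list alone 7 fell and 1 rose. The call of Il12a held in 1 of 6 cases with an array left out and in 3 of 9 other settings, with adjusted p up to 0.208. Without DKO replicate 3 the median of the list was -0.41. The recombinase gene Rag1 (-1.69) and the polymerase gene Dntt (-0.92) did not pass over all probe sets. The B lineage list was lower in 14 of 17 genes (median -0.71, adjusted p = 0.0110, and 0.678 with an estimated correlation), with 1 member past the threshold on both counts, the receptor gene Cd72 (-2.32 ± 0.38, adjusted p = 0.0117), whose call held in 4 of 6 cases with an array left out. Without WT replicate 2, the pool with the highest B lineage level, the list had a median of -0.08 and an adjusted p of 0.738, and without WT replicate 3 a median of -1.20. Its call also ended with array quality weights (-0.38, adjusted p = 0.0517) and with the mean over a gene's probe sets (-0.36, adjusted p = 0.223). The erythroid list was lower in 14 of 18 genes (median -0.50, adjusted p = 0.0395, and 0.759 with an estimated correlation). Carbonic anhydrase 2, Car2, fell from 20710 ± 1672 to 10091 ± 284 (-1.03 ± 0.12, adjusted p = 0.00207). It was the list's 1 member past the threshold, against 3 falls and 2 rises when adjusted over the list alone. The Car2 call was lost without an intensity trend (adjusted p = 0.131). Without WT replicate 2 the erythroid list had a median of 0.02 and an adjusted p of 0.978. Without DKO replicate 2 the list had a median of -0.38 and an adjusted p of 0.121. Its median was -0.75 without WT replicate 1, -0.999 without WT replicate 3 and -0.33 with no filter on low values. Its call was also lost with array quality weights (-0.42, adjusted p = 0.158), without an intensity trend (adjusted p = 0.146) and with the lowest 60% of probe sets left out (-0.68, adjusted p = 0.0731).

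**Figure D3:**
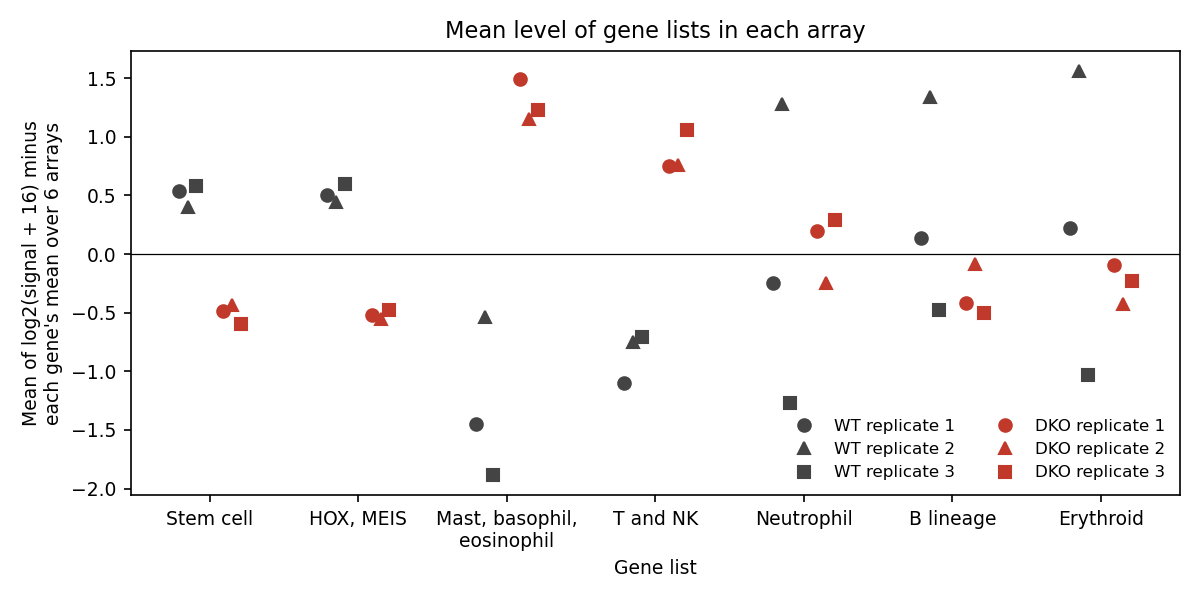
Mean level of 7 gene lists in each array, as the mean of log2(signal + 16) minus each gene's mean over the 6 arrays; grey symbols are WT, red are DKO, and the symbol shape gives the replicate number. The groups separate for the first 4 lists, while for the neutrophil, B lineage and erythroid lists WT replicate 2 lies highest, at 1.28, 1.34 and 1.56.

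Immediate early genes, which respond within minutes to signals, were lower in 19 of 21 cases (median -0.58, adjusted p = 4.99e-05, and 0.521 with an estimated correlation). The groups overlapped, as the mean level of this list in DKO replicate 1, 0.15, lay above that in WT replicate 3, -0.09. Jun was the 1 member that fell over all probe sets, from 5306 ± 1539 to 1945 ± 636 (-1.45 ± 0.28, adjusted p = 0.0281), and 5 fell when adjusted over the list alone. Fos and Fosb did not pass, at -0.55 and -0.09. In the quiescence list 13 of 18 genes were lower (median -0.40, adjusted p = 0.00369, and 0.223 with an estimated correlation). Foxo3, a transcription factor that keeps stem cells quiescent, changed by -0.88 ± 0.17 (adjusted p = 0.0297) and was its 1 call over all probe sets, with 3 when adjusted over the list alone. The other 2 of these 3, Ndn and Txnip, are also in the stem cell list, which shares 3 genes with this list. Without the shared genes 10 of 15 were lower (median -0.32, camera p = 0.0262 unadjusted, and p = 0.148 unadjusted with an estimated correlation). Jun stayed past the threshold in 2 and Foxo3 in 1 of 6 cases with an array left out, with adjusted p up to 0.172 and 0.206 over these and the other settings.

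Growth-related lists were higher by small amounts. The MYC and ribosome biogenesis list was higher in 21 of 23 genes (median 0.33, adjusted p = 7.91e-05, and 0.342 with an estimated correlation), with the nucleolar gene Nolc1 (0.93 ± 0.20, adjusted p = 0.0466) its 1 rise on both counts. That call held in 1 of 6 cases with an array left out and in 5 of 9 other settings, with adjusted p up to 0.211. The other Nolc1 probe sets, at 0.13 and 1.13, did not pass (adjusted p = 0.901 and 0.317). Glycolysis genes had a median of 0.25 (17 of 21 higher, adjusted p = 0.00394, and 0.179 with an estimated correlation), and 0 rose over all probe sets while 5 rose when adjusted over the list alone. Pfkp (0.98 ± 0.22) and Pkm (0.80 ± 0.18) had adjusted p of 0.0560 and 0.0565. DNA replication genes had a median of 0.19 (24 of 28 higher, adjusted p = 0.00667, and 0.342 with an estimated correlation) and oxidative phosphorylation genes of 0.21 (59 of 81 higher, adjusted p = 9.33e-04, and 0.678 with an estimated correlation), with 0 members past the threshold on either count. Rrm2 (0.67 ± 0.24, adjusted p = 0.227), Gins1 (0.48 ± 0.18, adjusted p = 0.259), Uqcrq (1.05 ± 0.32, adjusted p = 0.153) and Atp5o (0.72 ± 0.22, adjusted p = 0.157) had their smallest p. Oxidative phosphorylation had a median of 0.09 (adjusted p = 0.0890) without WT replicate 1 and of 0.12 (adjusted p = 0.117) without DKO replicate 3. Median centring raised the medians to 0.29 for DNA replication and 0.32 for oxidative phosphorylation.

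The other 14 lists did not pass. Medians and adjusted p were 0.17 and 0.131 for mitosis, 0.15 and 0.194 for cyclins, 0.10 and 0.296 for apoptosis, 0.12 and 0.553 for megakaryocytes, 0.11 and 0.553 for stroma and endothelium, 0.03 and 0.611 for niche adhesion, -0.02 and 0.614 for inflammatory NF-kB targets, and -0.19 and 0.633 for TGF-beta and BMP targets. They were -0.02 and 0.773 for heat shock, -0.09 and 0.856 for chromatin and DNA methylation, -0.21 and 0.856 for interferon response, -0.14 and 0.856 for p53 targets and -0.11 and 0.0902 for ribosomal proteins, besides the neutrophil list. Median and mean differed in sign for stroma, niche adhesion, NF-kB and TGF-beta lists, and the interferon test leaned higher against its median and mean. Single members changed: the cytokine Il6 rose by 3.54 ± 0.51 (263 ± 137 against 6.50 ± 4.81 in WT, adjusted p = 0.00581, and 2.13 with a pseudocount of 64), the p53 target Perp by 2.40 ± 0.27 (adjusted p = 0.00143), the lymphoid regulator Id2 by 2.54 ± 0.37 (adjusted p = 0.00614) and the integrin gene Itgb3 by 1.29 ± 0.27 (adjusted p = 0.0409). Emcn, of the stroma and endothelium list, fell (-1.95 ± 0.35, adjusted p = 0.0206). With an array left out Perp stayed past the threshold in all 6 cases, Id2 in 5, Emcn in 2 and Itgb3 in 1, and Il6 in the 3 that measured it.

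In all, 16 of 30 lists passed with camera's preset correlation, 9 higher and 7 lower. With an estimated correlation 3 held, the stem cell, T and NK cell and HOX and MEIS lists. The estimated correlation of the stem cell list, -0.0057, lay below the preset 0.01, yet its unadjusted camera p was 8.02e-04 against 6.39e-16. The lymphoid-primed progenitor list, at -0.028, lost its call too. Calls lost in this setting therefore cannot be put down to correlation between genes alone. With fry, which tests whether a list's genes move on balance to 1 side and compares no list with other genes, 6 passed. Other splits of the 6 arrays gave up to 13 lists with the preset correlation.

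No enrichment of genes beside the targeted loci was detected among the changed genes. Within 10 Mb of Nr4a1 or Nr4a3, by gene order and distance in assembly GRCm38.p6, 1 of 206 measured genes changed, against 193 of 11259 elsewhere (Fisher's exact test, two-sided, p = 0.270, odds ratio 0.280, confidence interval 0.00701 to 1.59). The 1 gene was Cd72, near Nr4a3. Of the sex-linked genes measured in these pools, the Y-linked Kdm5d (-1.04 ± 0.32, adjusted p = 0.151) and Uty (-0.75 ± 0.31, adjusted p = 0.288), Xist (0.16) and Eif2s3y (-0.08) did not pass. Kdm5d and Uty were lower in every DKO pool than in any WT pool, and their other tested probe sets were lower without passing. The fit recovered 6% of simulated log2 changes of 1. These values therefore cannot show that the groups were alike in sex.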

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

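All alternatives but those named as later were chosen before the data were examined. Nr4a1 was lower in every setting that measured it (log2 -5.75 to -3.72, adjusted p up to 0.00449), and the 60% filter removed it. Nr4a3, always taken from a fit over all probe sets so that the filters leave it as it is, did not pass in any setting. The 197 changed genes, among those measured, kept their sign in every setting except 1 gene in the mean over probe sets. Counts of changed probe sets and genes moved from 370 and 197 to 208 and 117 with no filter, 88 and 40 without a trend, 563 and 308 with array quality weights and 738 and 385 at a threshold of 0.10. With an array left out they ranged from 104 to 469 probe sets and 53 to 268 genes. Of 57 named genes past the threshold, 24 stayed past it whichever array was left out and none changed sign. The replicate numbers share no stated source; deviations of same-numbered arrays correlated at 0.14, -0.03 and 0.05, and not every array correlated best with its own number. The replicate block gave 167 genes and 17 lists. The number of lists past the threshold was 15 to 17 in the other settings but 3 with an estimated correlation and 6 with fry. The stem cell list kept a median of -1.09 to -0.84 with an array left out, and -0.86 over 17 brighter members, an alternative chosen after seeing the data. The gap between the risen lists and the other mature-cell lists was 2.28 and, with the monocyte list added, 2.11, also chosen after seeing the data. So were the quiescence list without genes of the stem cell list (-0.32) and the gap between the granulocyte-monocyte progenitor and stem cell lists with an array left out (1.65 to 2.27). The side tested by camera, which can differ from the sign of the median, turned for the erythroid list and for 9 lists not past the threshold. With an array left out their medians ranged from -0.999 to 0.0172 for erythroid, -0.661 to 0.855 for neutrophil, -0.214 to -0.0850 for interferon, -0.552 to 0.278 for stroma, -0.0636 to 0.0174 for niche adhesion, -0.304 to -0.00162 for TGF-beta, -0.0453 to 0.0240 for chromatin, -0.179 to 0.155 for NF-kB, -0.116 to -0.00686 for heat shock and -0.223 to -0.0612 for p53 targets. The p53 list also turned with a pseudocount of 1 (-0.105), the 60% filter (-0.0282), array weights (-0.120) and fry (-0.143), and the heat shock list with the 60% filter (0.110) and the mean over probe sets (0.0913). Leaving an array out leaves fewer values to test, yet without WT replicate 2 the count rose from 197 to 268 genes. The cause of the moves between settings was not tested. Odds ratios near the loci were 0.392 and 0.332 in 5 and 20 Mb windows and 0.783 at p 0.01. The filter left out probe sets with a mean log2 value under that of a signal of about 53.2. This limits what can be said of Nr4a3 and other dim genes.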

Other observations

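Gene groups written down after the data were seen, with several members put in because they had passed, add detail to the comparison; their counts are no independent evidence. Of 8 eosinophil genes 5 rose, among them Siglecf, an eosinophil surface lectin, from a signal of 404 ± 103 to 4169 ± 468 (SD, n = 3 each; log2 3.34 ± 0.25 SE, limma adjusted p = 6.87e-05), and the ribonuclease gene Ear3 (2.97 ± 0.44). The major basic protein gene Prg2, at 16092 ± 1324 against 4376 ± 4909, did not pass (adjusted p = 0.0653), nor did Il5ra (1.96 ± 0.49, adjusted p = 0.0818) and Prg3 (2.90 ± 0.76, adjusted p = 0.0975). Among effector genes of NK and T cells 7 of 11 rose, with Eomes at 2.79 ± 0.47 and the interferon gene Ifng at 3.34 ± 0.57, while perforin, Prf1, had 0.08 ± 0.29. Of 13 immunoglobulin and plasma cell genes 7 rose, all of them immunoglobulin or J chain genes, among them Igk (3193 ± 2148 to 18174 ± 6571, adjusted p = 0.0123). The IgM heavy chain gene Ighm, outside that group, had -0.05 and did not pass. The 6 others did not pass either: Prdm1, Xbp1 and Edem1 were higher in every DKO array than in any WT array, at 1.10, 0.88 and 0.81, Sdc1 was lower in every DKO array, at -0.74, and Irf4 and Mzb1 had 0.05 and -0.07. In the antigen presentation group 4 genes rose, H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and H2-Ob fell by 1.26 (-1.26 ± 0.26, adjusted p = 0.0420). Their regulator Ciita had 0.09 ± 0.46. Its signals, 54.8 ± 20.2 in WT and 57.4 ± 7.0 in DKO, lay near the filter limit of about 53.2, so a change in it could be missed.

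Genes of serine, other amino acid and folate metabolism and of the endoplasmic reticulum were higher in 14 of 16 cases, and 7 rose. Psat1 rose from 4550 ± 893 to 8659 ± 318 (0.94 ± 0.17, adjusted p = 0.0196), Mthfd2 by 1.33 ± 0.26, Bcat1 by 1.94 ± 0.38 and the chaperone Sdf2l1 by 1.76 ± 0.38. Phgdh, the first enzyme of serine synthesis, had -0.06 ± 0.26 and the chaperone Hspa5 0.21 ± 0.17. Of 14 genes used widely by progenitors, each by its brightest probe set, 0 passed by limma and 6 were higher. Of these 6, Mpo, Prtn3 and Elane are also in the granulocyte-monocyte progenitor list. Myb was at -0.02 ± 0.14, Runx1 at 0.11 ± 0.16, Cdk6 at 0.69 ± 0.17 (adjusted p = 0.0713) and Cd34 at -0.78 ± 0.18 (adjusted p = 0.0672). Lmo2, Sox4, Kit, Cd93 and Cd27 were at -0.50, -0.89, -0.60, -0.95 and -0.61. These and Cd34 were lower in every DKO array than in any WT array, while Cdk6 and Prtn3 were higher in every DKO array. Such a lack of overlap was seen in 22.0% of all genes. A second Cdk6 probe set rose, at 1.28 ± 0.22 (adjusted p = 0.0175), and another, at 0.92 ± 0.24, did not pass (adjusted p = 0.0920).

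The tests in the next paragraphs were chosen after the results were seen; the lists other than the progenitor group were fixed before. Other splits of the 6 arrays into 3 and 3 gave at most 0 probe sets and 0 genes, against 370 and 197 in the real split, and at most 13 lists, against 16. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits cannot give a share under 0.1. Of the 16 lists, 10 had their largest shift in the real split; the immediate early, granulocyte-monocyte progenitor, monocyte, oxidative phosphorylation, B lineage and erythroid lists did not.

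The first pattern is the rise of basophil, mast cell, eosinophil and T or NK cell markers. A lower share of stem and progenitor cells would raise markers of all other cells present alike. The mean shift of these lists was log2 2.28 above that of the neutrophil, B lineage, erythroid, stromal and megakaryocyte lists. The range 2 SE either side, a rough interval with n = 3, was 1.79 to 2.77. The gap was 2.11 (1.61 to 2.60) with the monocyte, macrophage and dendritic cell list added to them, and 1.22 (0.69 to 1.75) above that list alone. The rise was thus not alike across these lists. This cannot exclude a lower stem cell share, since a sort against lineage markers may remove cells of the compared lists. WT replicate 2 also had the highest neutrophil, B lineage and erythroid levels, at 1.28, 1.34 and 1.56. More basophils, eosinophils and T or NK cells in the sorted fraction may explain the rise. Of the markers 91.9% (34 of 37) were higher, but these lists define the pattern and cannot test it. Of their bright genes, Gzma went from 362 to 5450 while Prg2, already at 9998 in WT replicate 2, did not pass, and such levels decide nothing. The sort against lineage markers should remove most mature T cells, and whether it removed basophils and eosinophils is not given in the sources used here, and more such cells and more of these transcripts per cell cannot be told apart in pooled RNA.

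The second pattern is the fall of the stem cell list. RNA of mature cells could dilute all stem and progenitor RNA. It would then lower the granulocyte-monocyte progenitor list as much, unless those cells made its genes too. That list lay 1.91 above the stem cell list on the log2 scale (2 SE either side, 1.04 to 2.78), although its levels overlapped between the groups. The gap was 1.65 to 2.27 with an array left out, and 1.82 without 4 genes also used by T or NK cells. Genes that mast cells, basophils or eosinophils may also make were not taken out, so the gap cannot show that dilution is small. The 11 progenitor genes in neither list had a median of -0.50 with 3 higher, against -0.98 in the stem cell list, and a mean of -0.35, 0.66 above that of the stem cell list (0.49 to 0.83), so a part of the fall may still come from dilution, and how large a part is open. No single array carried it: the weakest median was -0.84 with an array left out, with adjusted p up to 4.52e-12. A smaller share of stem cells within the sort and a lower level of these genes per cell both stay open, as hypotheses.

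The third is whether DNA of another strain beside the targeted loci makes up the changed genes, since the DKO mice had a mixed background. Of 194 changed genes with a position, 2 (1.03%) lay within 20 Mb of Nr4a1 or Nr4a3, Cd72 and Pnrc1. That window held 345 measured genes, against 11120 elsewhere. The other changed genes thus did not lie in such DNA within 20 Mb. Position cannot exclude a longer stretch of it or an effect of it on genes elsewhere. For Cd72 itself, which lies near Nr4a3, a strain difference stays open. Differences of unlinked strain DNA between the groups could not be tested.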
